A study of Mus musculus with 19 samples.

How the data were processed

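Marrow DNA of 19 pairs of mice was measured on 2-colour Agilent CpG island arrays. Each pair was a PU.1 knockdown and a wild-type animal, matched for age and sex per the labels. The ages given differ in preleukemic pair 1 (knockdown 4, wild type 5 weeks) and late pair 4 (27 and 28 weeks). Per the labels' protocols, methyl-CpG immunoprecipitation enriched densely methylated DNA, about 30 ng was labelled by random priming, and knockdown DNA took Alexa 5 (red) and wild-type DNA Alexa 3 (green). No array had the dyes exchanged, so a dye effect of a probe adds to every stage mean and cancels only between stages. Homozygous knockdown and wild-type littermates came from heterozygous parents. Pairs of a stage are numbered biological replicates in the labels.

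Per the file headers, Agilent Feature Extraction 10.5.1.1 produced the deposited intensity values: background was subtracted, spatial and multiplicative trends were removed and the dyes were normalized linearly within each array. Raw spot and background intensity columns are in the same deposited files. The deposited series table holds the authors' log2 ratios of the same arrays. Set against the scanner values, its columns ran in the same direction, with r of 0.418 to 0.897 across probes and a slope at the brightest probes of 0.534 to 1.15. Its column medians lay between -0.0118 and 0.0438. How low signals were shrunk there, and on what scale, is not given in the sources used here, so it served as an alternative. The files also carry the scanner's other values, 0 or 1 spot marks for signal well above background, saturation and uneven spots, per the file headers.

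From the processed intensities, log2 of red over green was taken, spots marked as uneven or as population outliers were left out (4 to 2599 per array), and each array was centred on its median, without loess or quantile steps. Saturated spots, 0 to 13 per array, were kept. A probe was kept where either channel was well above background on at least 4 of 19 arrays. Of 88737 probes, 426 had no position and 74613 were kept. Probes of a chromosome with starts at most 500 bp apart formed a region, and the region's value was the mean of its probes. Regions with at least 3 probes were tested, 12606 of 15615, with a median of 5 probes and 587 bp. Of these, 10034 carried 1 gene name, 1193 several and 1379 none. Coordinates are those of the array's probe names. Gene names are the array's own. A RefSeq gene table supplied newer symbols: of single names, 6767 were current, 1369 were older synonyms and 129 were not matched. The files' annotation of position within a gene was empty, so the planned split by promoter or gene body was reduced to regions with and without a gene name. Chromosome Y had no region.

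Each stage mean was tested against 0, and stages against each other, with limma 3.58.1 (lmFit and eBayes in R 4.3.3) on all 19 arrays with 1 mean per stage, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over 64 tests, 16 lists in 4 contrasts. No list passed with an estimated correlation. SDs per array were compared by exact permutation, adjusted over the 3 pairs of stages. Design, lists, alternatives and the rule for named regions were fixed before the data were examined. The rule named the PU.1 gene, the 12 largest gains and losses per stage among single-gene regions past the threshold with 1 sign on all arrays of the stage, at most 4 members per list and contrast by adjusted p, and, where fewer than 3 passed in a direction between late and preleukemic pairs, the 3 with the smallest p. List members named outside this rule, because their list had 5 or fewer that moved their way, were chosen after their values were seen; so were the regions passing in all 3 stages and the late minus early region.

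Slides and scan order came from the file headers. Of 10 slides, 3 held a preleukemic and a late array, 2 a preleukemic and an early array, and 2 held late arrays alone and were scanned last. Slide entered as a fixed block between stages and as a random block (correlation 0.105) for stage means. The replicate number was a block in an alternative. It did not pair arrays: correlations of same-numbered deviations exceeded 0.1 in 4 of 5 preleukemic and early pairs, in 1 of 7 preleukemic and late pairs and in 1 of 5 early and late pairs. Other alternatives were no centring, normexp background correction with an offset of 50, within-array loess, other probe filters, spots marked uneven kept, the authors' values, no sex chromosomes, a 1000 bp gap, single probes, an absolute log2 ratio of at least 0.5, stages fitted alone, array weights, eBayes with trend and robust, an age covariate and leaving out each array.

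The steps were tested on simulated data in 12606 regions, drawn independently of each other with each region's own SD per stage. Of 50 regions changed by 1 on the log2 scale in 1 stage, 34 were recovered in preleukemic, 28 in early and 32 in late arrays, with 8, 11 and 312 unchanged regions called. With late arrays alone in the fit, 23 were recovered and 8 called in error. Of 50 regions changed by 1 in late arrays, 27 were recovered in the late minus preleukemic contrast, with 50 unchanged regions called in error. The late arrays' wider spread thus makes the fit over all stages too permissive for them. The simulation left out that late arrays differ in spread (SD over regions 0.414 to 1.89) and that regions move together (r = 0.827 between late replicates 4 and 7). The 312 calls are therefore no estimate of the false calls in the real late fit.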

Results

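The series profiled DNA methylation in bone marrow of mice with a knockdown of PU.1, a transcription factor of the ETS family that directs myeloid and B lymphoid differentiation. Methyl-CpG immunoprecipitation retains DNA fragments dense in methylated CpG sites. It was applied to marrow of a knockdown mouse and of its matched wild-type mouse, both on the Balb/c background. The 2 enriched fractions of a pair were labelled with different dyes and hybridised together to a CpG island array. There were 7 pairs at the preleukemic stage, 5 at the early leukemic stage and 7 at the late leukemic stage, 19 arrays in all. The disease-state label of the middle stage reads intermediate leukemia, while its titles say early leukemic. Knockdown mice were 4 to 18 weeks old in preleukemic pairs, 4 to 12 in early pairs and 12 to 27 in late pairs. Age thus differs with stage. The wild-type mouse had the same age, except in preleukemic pair 1 (knockdown 4, wild type 5 weeks) and late pair 4 (27 and 28 weeks). Values are log2 ratios of knockdown over wild type, with 0 at the median probe of each array, and a positive value means more methylated DNA in the knockdown. The regions tested were 12606 clusters of at least 3 neighbouring probes, of which 10034 carried 1 gene name. The wild-type channel stood well above background at 27.5% to 73.5% of probes per array and the knockdown channel at 57.4% to 80.7%. The number of arrays limits the precision of every value.

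The PU.1 gene itself, listed on the array as Sfpi1 (now Spi1), carried less methylated DNA in knockdown marrow at all 3 stages. Its region on chromosome 2 (start 90915973, end 90916423, 4 probes; genome build not given in the sources used here) had a mean log2 ratio of -2.14 (SE 0.36, n = 7) in preleukemic pairs, -2.22 (SE 0.42, n = 5) in early pairs and -2.72 (SE 0.36, n = 7) in late pairs. In the order of the replicate numbers, the preleukemic arrays read -1.35, -1.80, -2.92, -3.74, -2.05, -2.57 and -0.53. The early arrays read -2.07, -2.23, -2.35, -2.80 and -1.68, and the late arrays -4.46, -2.60, -2.48, -1.11, -2.29, -4.17 and -1.93. All 19 ratios were below 0, and the limma adjusted p was 0.0052, 0.0334 and 0.000184. A methylation ratio does not measure PU.1 expression, and the place of these probes relative to the engineered allele is not given, so the value checks neither the knockdown nor the labels. The preleukemic call at Sfpi1 ended in 1 of 14 alternatives, normexp background correction (log2 ratio -0.50). The early call is weaker: it ended in 5 of 14, among them normexp (-0.88) and the authors' processed values (-1.47), and without each of the 5 early arrays in turn (adjusted p = 0.102 to adjusted p = 0.187).

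Comparing knockdown with wild-type marrow before leukemia asks which methylation differences precede the disease. In preleukemic pairs, methylated DNA rose most at Tnfaip8, a TNF-induced regulator of cell death, with a log2 ratio of 4.42 (SE 0.54, 21.5-fold; 1.53 under normexp and 1.94 with the authors' values). It also rose at Fosb, an AP-1 subunit (3.24, SE 0.29), Stc2, a secreted glycoprotein hormone (2.99, SE 0.42), Cdh15, which encodes M-cadherin (2.87, SE 0.42), and Bsn, a presynaptic scaffold protein (2.40, SE 0.22). It fell most at Ebi3, a subunit shared by the cytokines IL-27 and IL-35 (-3.61, SE 0.18), at the potassium channel gene Kcnk12 (-3.58, SE 0.41) and at Antxr2, an anthrax toxin receptor (-3.36, SE 0.33). Among the smaller losses, Ncf1, a cytosolic subunit of the phagocyte NADPH oxidase, stood at -2.60 (SE 0.32), Arhgap9 at -2.43 (SE 0.32), and Gfi1, a repressor needed for granulocyte development, at -1.60 (SE 0.18). Each of these 11 regions had its sign in 7 of 7 arrays, as the naming rule required. Under normexp the calls at Kcnk12 (-0.72, adjusted p = 0.0604) and Arhgap9 (-0.77, adjusted p = 0.156) ended, among 11 of the 27 preleukemic calls that the naming rule chose, and the losses that stayed were smaller (Ebi3 -1.90, Antxr2 -1.02, Ncf1 -1.09, Gfi1 -0.30).

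Further preleukemic gains were found at Adam11 (2.78), Rap2ip (now Rundc3a, 2.72), Mcf2l (2.58), B3galnt1 (1.94), 1700012A16Rik (now Shcbp1l, 1.83), Grrp1 (1.81) and Myh14 (1.62). Further losses were found at Tead3 (-2.75), Schip1 (-2.14), Abhd9 (now Ephx3, -1.46) and Nt5c (-0.67). Several of these calls ended when 1 array was left out. Those at 1700012A16Rik and Schip1 ended without any 1 of 6 of the 7 arrays, that at B3galnt1 without any 1 of 5, those at Mcf2l and Nt5c without any 1 of 3, and that at Tead3 without either of 2. In total 67 of the 12606 regions passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 44 gained and 23 lost. The count was 39 without preleukemic replicate 3, 43 without replicate 5, 40 without replicate 6, 44 without replicate 7 and 137 without replicate 4. It was 2109 (2002 gained) under normexp, 148 (67 gained) with the authors' values, 23 with trend and robust variances, 1133 with array weights and 320 with preleukemic arrays alone in the fit.

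Few members of the 16 gene lists passed the test in preleukemic pairs. Among myeloid regulators, Sfpi1 and Gfi1 fell (2 of 39 regions; 4 adjusted over the list alone), and among myeloid effectors Ncf1 fell (1 of 12, and 1 adjusted over the list alone). Of the 66 regions of Hox genes, the patterning factors that also mark blood progenitors, Hoxb5 rose (0.93, SE 0.20). Sp7, an osteoblast transcription factor, rose among 12 stromal and endothelial regions (1.38, SE 0.24), and Rassf1, a tumour suppressor, fell among 50 regions of genes often hypermethylated in leukemia (-0.65, SE 0.14). Over the list alone these counts were again 1 each. As a set, 38 regions of imprinted genes shifted up (median log2 ratio 0.21, camera adjusted p = 1.8e-07), with the Cdh15 region as the 1 member past the threshold. The 23 germ cell gene regions shifted up (median 0.16, adjusted p = 0.0031, no member past the threshold), as did stromal and endothelial genes (median 0.04, adjusted p = 0.0281). The 22 regions of DNA methylation machinery shifted down (median -0.11, adjusted p = 0.0463), with no member past the threshold. With an estimated correlation between members none of the 4 passed (adjusted p = 0.63 for imprinted genes, stroma and machinery, and adjusted p = 0.662 for germ cell genes). The calls at Hoxb5 and Rassf1 are weak. That at Hoxb5 ended in 3 of 14 alternatives, turned to -0.15 where probes up to 1000 bp apart were joined, and ended without any 1 of 6 of the 7 arrays (adjusted p up to 0.145). That at Rassf1 ended in 6 of 14 alternatives, among them normexp (-0.11), and without any 1 of 5 arrays (adjusted p up to 0.163). The 4 list shifts ended under loess. Polycomb-type developmental factors and Hox genes did not pass as lists in preleukemic pairs (adjusted p = 0.0765 and adjusted p = 0.0987). They did shift up without a filter on dim probes (adjusted p = 0.0412 and adjusted p = 0.0301). Both also passed with the age covariate (camera adjusted p = 2.8e-12 and adjusted p = 2.1e-05). That fit gives a stage's value as predicted at the mean age of all 19 mice. Most preleukemic mice were younger, so the result rests in part on the slope with age over all stages.

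The early leukemic comparison asks which methylation differences are present at the stage that the titles call early leukemic. Methylated DNA rose at Tnfaip8 (log2 ratio 3.45, SE 0.64), Stc2 (3.12, SE 0.49), Fosb (3.10, SE 0.35), Cdh15 (2.99, SE 0.49), Rap2ip (2.74, SE 0.41), Adam11 (2.63, SE 0.48) and Bsn (2.49, SE 0.26). Smaller gains were measured at Grrp1 (1.70), Efcab4a (now Cracr2b, 1.65), Myh14 (1.59), Mapk11 (1.40) and Nfix (1.26). Losses were largest at Kcnk12 (-3.51, SE 0.48), Antxr2 (-3.38, SE 0.39) and Ebi3 (-3.07, SE 0.21), followed by Arhgap9 (-2.60), Ncf1 (-2.50), Sfpi1 (-2.22) and Fcho2 (-0.60). Every one of these regions had its sign in 5 of 5 arrays, as the naming rule required. Fosb, Bsn, Kcnk12, Antxr2 and Ebi3 stayed past the threshold without any 1 early array. The calls at Tnfaip8 (adjusted p = 0.0637 to adjusted p = 0.186), Efcab4a, Mapk11 and Sfpi1 ended whichever of the 5 was left out. With the replicate number as a block, 15 of the 19 early calls named here ended, and under normexp 8. In all, 28 of 12606 regions passed in limma, 20 gained and 8 lost. Sfpi1 was the 1 myeloid regulator region that fell (3 adjusted over the list alone), Ncf1 the 1 myeloid effector region that fell and Cdh15 the 1 imprinted gene region that rose (1 each over the list alone). Hox genes (median 0.01, mean 0.15) and germ cell genes (median 0.15) shifted up as lists, with camera adjusted p = 0.0465 and 0.0435 and with no member past the threshold over all regions or over the list alone. Neither passed with an estimated correlation (adjusted p = 0.845 and adjusted p = 0.838) or under loess, nor without chromosomes X and Y (adjusted p = 0.0536 and adjusted p = 0.0694). With the age covariate, Polycomb-type factors (camera adjusted p = 2.5e-12) and B cell genes (adjusted p = 0.0215), which did not pass here, passed upward. Values with that covariate are predictions at the mean age of all 19 mice. No early mouse was that old, so they extrapolate and are not shifts measured in early pairs. Imprinted genes passed under normexp (adjusted p = 8.8e-06) and without a filter on dim probes (adjusted p = 0.0122). Without early replicates 1 to 5 in turn the count of regions was 16, 15, 5, 11 and 9. It was 200 under normexp, 54 with the authors' values, 74 with the early arrays alone in the fit, 17 with age as a covariate, 11 with trend and robust variances and 4 with the replicate number as a block.

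Changed regions recurred from stage to stage, and 25 regions passed in all 3 stages in the same direction, 18 gained and 7 lost. The gains included Tnfaip8, Fosb, Stc2, Cdh15, Adam11, Rap2ip, Bsn, Grrp1, Efcab4a, Mapk11, Nfix, Myh14, Aebp1, Atp6v0a2, Lmna and Gm1679. In late pairs Tnfaip8 stood at 4.04, Fosb at 3.06 and Adam11 at 3.15. The losses were Ebi3, Kcnk12, Antxr2, Ncf1, Arhgap9, Sfpi1 and a region with no gene name on chromosome 6 (start 83407021). In late pairs Kcnk12 stood at -2.74 and Arhgap9 at -1.01. Of the 67 regions changed in preleukemic pairs, 26 were changed the same way in early pairs, against 0.0844 for independent lists of these sizes, and 60 in late pairs, against 12.0. All 44 preleukemic gains and all 23 losses had the same sign in early and in late pairs. The 26 regions shared by preleukemic and early pairs became 16, 13, 5, 9 and 9 without early replicates 1 to 5 in turn and 17 without preleukemic replicate 5, and the 60 shared with late pairs became 35, 39 and 36 without preleukemic replicates 3, 5 and 6. The stage tests share the same estimate of spread for each region, so a region of small spread passes more easily in every stage. The numbers for independent lists are therefore not a chance level. No array had its dyes exchanged, so a dye effect of a probe would recur in every stage.

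**Figure D1:**
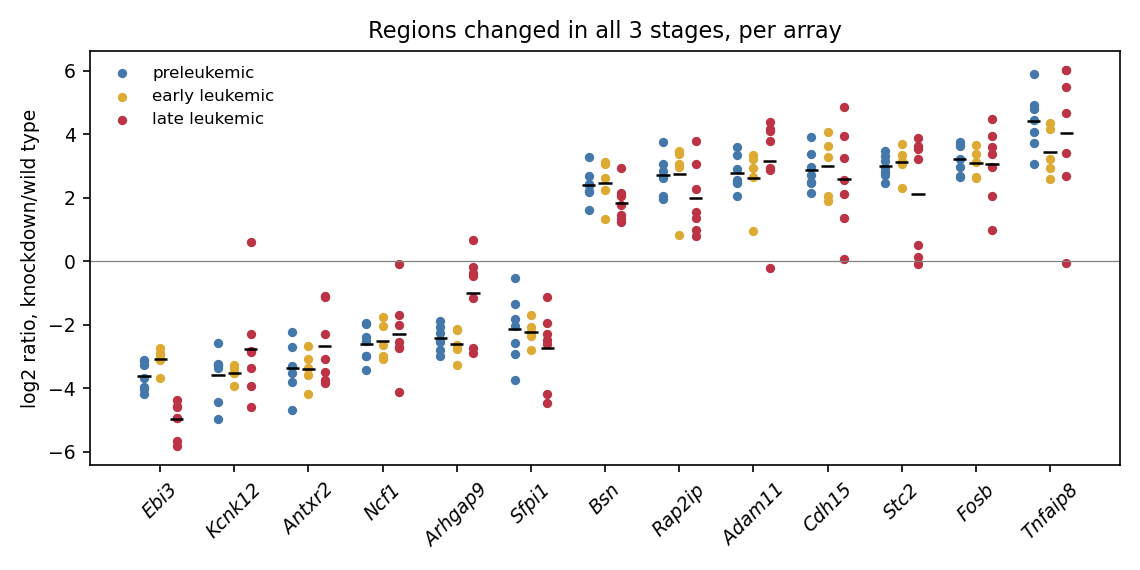
Log2 ratio of knockdown over wild type (vertical axis) at 13 gene regions changed in all 3 stages, 1 point per array and a bar for each stage mean. Ebi3 lies lowest, with a late mean of -4.97, and Tnfaip8 highest, with a preleukemic mean of 4.42.

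The late leukemic comparison asks how methylation differs once disease is advanced. Methylated DNA rose at Gm879 (now Shisa6, log2 ratio 3.54, SE 0.42), Frmd3 (3.39, SE 0.52), Rspo1, a Wnt pathway agonist (3.35, SE 0.38), the myogenic factor Pax7 (3.33, SE 0.43), Cdo1, a cysteine dioxygenase (3.28, SE 0.50), the homeobox genes Irx6 (3.27, SE 0.49) and Bsx (3.20, SE 0.43), and Nrg3 (3.19, SE 0.46). AW049604 (3.39), Col19a1 (3.26), Cbln4 (3.24) and Dbc1 (3.22) complete the 12 largest gains among single-gene regions with 1 sign on all 7 late arrays; Tnfaip8, above them at 4.04, was not of 1 sign. The loss at Ebi3 was the largest of the stage (-4.97, SE 0.18, 31.4-fold; -2.96 under normexp). Losses also included Def6 (-3.08, SE 0.53), Exosc2 (-2.68), Fbxl12 (-2.48), Rkhd4 (now Mex3a, -2.40), Sigirr, an inhibitor of interleukin-1 receptor signalling (-2.32, SE 0.33), Abhd9 (-2.23), Socs3, an inhibitor of cytokine signalling (-1.85, SE 0.24), and D630037F22Rik (now Tbc1d32, -1.78). Apart from Tnfaip8, each region named here had its sign in 7 of 7 arrays, as the naming rule required.

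Of the 12606 regions, 4334 (34.4%) passed in limma in late pairs, 2433 gained and 1901 lost. The balance turned with the processing: losses outnumbered gains without centring (2342 gained, 3196 lost) and without a filter on dim probes (2642 gained, 3166 lost). With the authors' values 2022 gained and 711 lost. Gained regions had a median log2 ratio of 1.59 and 97.4% of them reached a size of 0.5, while lost regions had a median of -0.41 and 29.2% reached that size. The sign was shared by 7 of 7 arrays at 776 gained and 826 lost regions. The counts rest on a spread estimated over all 3 stages: with late arrays alone in the fit 13 regions passed, among them Ebi3, Rspo1, Hoxb5 and Socs3, the 4 that passed of the 81 regions that the naming rule chose for this stage. With age as a covariate 53 passed, 13 of those 81 among them, with array weights 701 (54 of the 81), and with the 3 late arrays that shared a slide with another stage 292 (28 of the 81). That last choice was made after seeing the data. Late replicates 4 and 7 weighed most on the count, which was 2790 without the former and 2841 without the latter. These 2 arrays shared 1 slide, the last scanned, and correlated at r = 0.827 over regions, the highest of all pairs of arrays. Late replicate 4 also had the highest background noise in the knockdown channel, 22.2, and 2599 marked spots. An effect of that slide cannot be told apart from what the 2 mice share.

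Polycomb-type developmental transcription factors, families that Polycomb proteins often mark in stem cells, rose as the broadest group in late pairs. Of their 261 regions, 186 rose and 3 fell (203 and 5 adjusted over the list alone), with a median log2 ratio of 1.36 and a camera adjusted p of 1.1e-24. Examples are Otx2 (2.81, SE 0.35), Isl2 (2.31, SE 0.32) and Pax7, while those that fell were Tbx21 (-0.68) and a pair of regions at Neurod2 (-0.25 and -0.48), of which another region rose (1.57). Of the 66 Hox regions, 36 rose and 2 fell (43 and 2 over the list alone), with a median of 0.94 and adjusted p = 1.8e-08. Hoxd12 (2.13), Hoxc12 (2.00), Hoxd1 (1.99) and Hoxb5 (1.42) rose, and a pair of regions of Hoxb3 fell (-1.11 and -0.76) while another rose (1.35). The late arrays differed widely here, and replicates 4 and 7, the highest for both lists, shared 1 slide. The median over Polycomb-type regions was 0.07, 0.11, 0.55, 3.46, 1.39, 0.23 and 3.42 in late replicates 1 to 7, and the Hox median was -0.06, 0.11, 0.37, 2.75, 0.96, 0.01 and 2.69. Neither list passed with an estimated correlation (adjusted p = 0.63 for both). Over all lists and contrasts, 25 of 64 list shifts passed, against 12, 14 and 16 without late replicates 4, 5 and 7 and 19 (15 up, 4 down) without chromosomes X and Y.

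**Figure D2:**
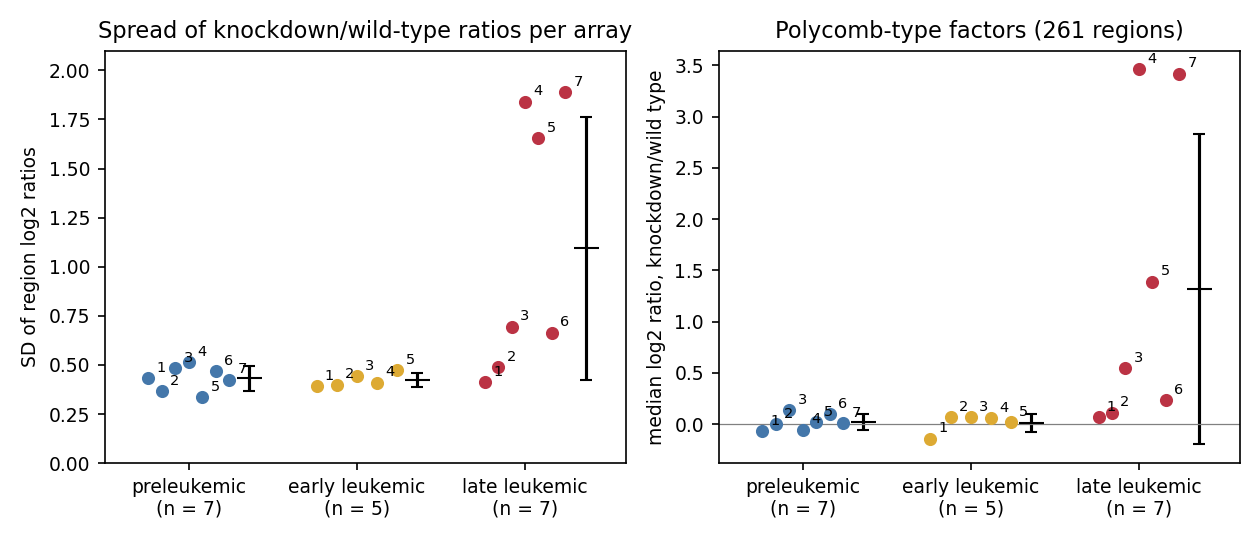
Left, standard deviation of region log2 ratios per array by stage; right, median log2 ratio of 261 Polycomb-type regions per array, with replicate numbers beside the points and the stage mean and SD as a bar. Late replicates 4 and 7 lie highest on the right, at 3.46 and 3.42.

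Genes with roles in blood lineages moved in both directions. So did the regions as a whole, of which 2433 gained and 1901 lost among 12606, so this is not particular to these lists. In the B cell list 6 of 11 regions rose and 1 fell (the same counts over the list alone; camera adjusted p = 0.036), with gains at Pax5, the B lineage commitment factor (3.12, SE 0.47), and at Ebf1 (1.67, SE 0.24) and a loss at a region between Btk and Rpl36a (-0.85). Of 41 stem and progenitor regions, 16 rose and 4 fell (18 and 4 over the list alone; adjusted p = 0.0415), with Prdm16 (2.59, SE 0.43), Gata2 (2.83-fold) and Pbx3 (0.88) rising and regions of Mycn (-1.22, SE 0.22), Myc (-0.46) and Hoxb3 falling. Of 39 myeloid regulator regions, 12 fell and 4 rose, over the list alone too, and the list as a whole did not shift (adjusted p = 0.324). Sfpi1, Gfi1 (-1.49, SE 0.18) and Cebpb (-0.40, SE 0.07) fell and Egr3 rose (1.58, SE 0.29). Of 12 myeloid effector regions 3 rose, among them a region between Cd14 and Tmco6 (0.35) and Prtn3 (0.62), and Ncf1 fell (-2.27). The call at Prtn3 ended in 10 of 16 alternatives and without late replicate 4, 5, 6 or 7. In the T and NK cell list 5 of 14 regions rose, at Bcl11b (2.25) and Gata3 (1.75), and 3 fell, at Cd247 (-0.37), Tbx21 and another Gata3 region (-1.14). In the erythroid and megakaryocyte list 6 of 21 rose, among them Tal1 (1.52) and Ank1 (1.82), and 3 fell, at regions of Epb4.1 (-0.45), Epb4.9 (-0.26) and Epor (-0.46). Counts over the list alone were the same for these 3 lists, whose adjusted p values were 0.989, 0.649 and 0.504. The B cell and stem cell lists did not pass with an estimated correlation (adjusted p = 0.63 and adjusted p = 0.744) or under loess, nor did the B cell list under normexp or the stem cell list without chromosomes X and Y (adjusted p = 0.0536). With the age covariate neither passed (adjusted p = 0.112 and adjusted p = 0.124). Nor did either pass with only late replicates 1 to 3, those on slides shared with other stages (camera adjusted p = 0.505 and adjusted p = 0.644).

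Inhibitors of Wnt signalling rose at 12 of 29 regions and fell at 1 Dact3 region (-0.36), with camera adjusted p = 0.0147; Sfrp1 (2.62, SE 0.54), Dact2 (2.27), Sox17 (2.09) and Sfrp5 (2.02) led. Genes often hypermethylated in leukemia rose at 19 of 50 regions and fell at 8 (21 and 8 over the list alone; adjusted p = 0.0281), with Hs3st2 (2.89, SE 0.41), Cdh13 (2.84, SE 0.52), Trp73 (2.42) and Hic1 (1.16) rising. Those that fell were Cdkn1a, Rassf1 (-0.56), Rb1, Cdkn1b, a pair of regions at Junb (-0.49 and -0.37) and a pair at Hic1 (-0.36 and -0.21). Stromal and endothelial genes rose at 6 of 12 regions (8 rose and 1 fell over the list alone; adjusted p = 0.036), among them Pdgfra (1.52), Cxcl12 (1.58), Sp7 (1.23) and Foxc1 (0.89). The call at Cxcl12 ended in 4 of 16 alternatives and without late replicate 4 or 7 (1.04 without the latter), and that at Foxc1 in 4 of 16. Imprinted genes rose at 9 of 38 regions, including Zim1 (2.95) and Grb10 (2.45), and fell at Mcts2 (-0.52), Usp29 (-0.42) and a Cdh15 region (-0.36), and the list did not pass (adjusted p = 0.272). It did pass under normexp (adjusted p = 3.8e-07), without a filter on dim probes (adjusted p = 0.027) and with the age covariate (adjusted p = 0.00229). Of 23 germ cell regions Tdrd6 rose (1.26) and Sycp3 fell (-0.33, but 0.74 under normexp), neither past the threshold over the list alone, and the list did not shift (adjusted p = 0.614). Wnt counts over the list alone were the same, and 8 imprinted regions rose and 3 fell over that list. The Wnt, tumour suppressor and stromal lists each had adjusted p = 0.63 with an estimated correlation. Of these 3, the tumour suppressor list passed under within-array loess but not under normexp. With the age covariate the tumour suppressor (adjusted p = 0.0769) and stromal lists (adjusted p = 0.0567) did not pass. With only late replicates 1 to 3, those on slides shared with other stages, none of the 3 passed. The Wnt, tumour suppressor and stromal lists then had camera adjusted p = 0.139, 0.175 and 0.385.

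Small losses were found at genes of cell division, DNA methylation and general upkeep. Cell cycle regulators fell at 12 of 30 regions (14 over the list alone; camera adjusted p = 0.0078), with Cdkn1a (-0.93, SE 0.29, but 0.15 under normexp), Rb1 (-0.54, SE 0.12), Cdkn1b (-0.39) and Chek2 (-0.38, but 0.0027 under normexp) as examples. In the list named DNA methylation machinery, which is not limited to enzymes that methylate DNA, 7 of 22 regions fell (7 over the list alone, camera adjusted p = 0.036). Among them were Mbd2 (-0.60, with the wild-type signal well above background on 3 of 7 arrays), Hells (-0.35), Ezh2 (-0.30, but 0.0014 under normexp) and the maintenance methyltransferase gene Dnmt1 (-0.29). Constitutively used genes, whose CpG islands usually lack methylation, fell at 5 of 21 regions (5 over the list alone; adjusted p = 0.0281): Pgk1 on chromosome X (-0.79), Tubb5 (-0.78), Eef1a1 (-0.31), a region of Rps18 and Vps52 (-0.44) and 1 of Pias4 and Eef2 (-0.37). Many of these small losses are weak: the call ended in 6 of 14 alternatives at Pgk1, in 5 of 16 at Eef1a1, Hells and Cdkn1b, in 5 of 15 at Mbd2 and in 4 of 15 at Tubb5. It also ended without late replicate 7 at Eef1a1 and Hells and without late replicate 4 or 5 at Mbd2. At Ezh2 the call ended without any 1 of 3 of the 7 late arrays (limma adjusted p up to 0.0936), and at Cdkn1b without 1 (adjusted p = 0.0551). Under normexp, which moved the median of all regions in late pairs from -0.06 to 0.07, 5 constitutive regions rose and 6 fell, and 4 machinery regions rose and 11 fell. Without centring that median was -0.18. None of these 3 lists passed with an estimated correlation (adjusted p = 0.63) or under loess. The machinery list did not pass without chromosomes X and Y (adjusted p = 0.0536) or with the age covariate (adjusted p = 0.0882). With only late replicates 1 to 3, the cell cycle, machinery and constitutive lists did not pass (camera adjusted p = 0.458, 0.139 and 0.338).

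**Figure D3:**
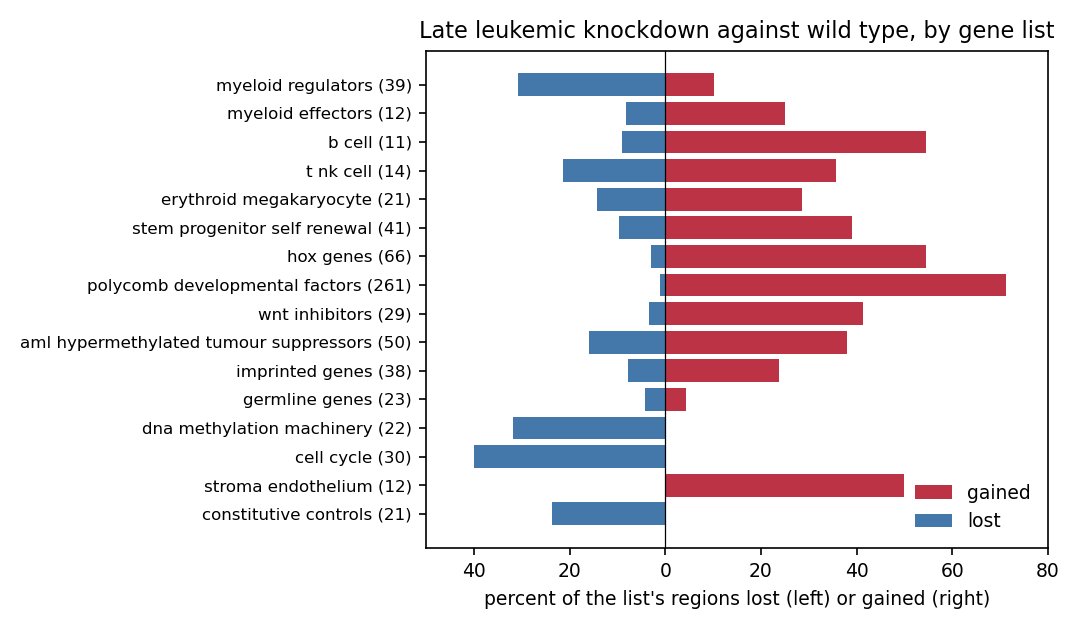
Percent of each list's regions that gained (right) or lost (left) methylated DNA in late leukemic pairs, with the number of regions in brackets. Polycomb-type factors reach 71.3% gained, and cell cycle regulators have the highest share lost, 40%.

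Whether the ratio itself differed between stages was tested directly. Ebi3 was the 1 region of 12606 that passed, with a log2 difference of -1.90 (SE 0.27, limma adjusted p = 0.0209) between late and early pairs. Its means were -3.07 in early and -4.97 in late pairs, and its difference between late and preleukemic pairs was -1.36 (adjusted p = 0.0863). No slide held both an early and a late array, and on the 3 slides with a preleukemic and a late array the late value of Ebi3 lay lower by -0.36, -0.38 and -0.62. The late minus early call ended with slide as a fixed block, with loess and with the authors' values, where 0 regions passed. The count was 0 as well with single probes, stages alone, array weights, trend and robust variances, the age covariate and the replicate block. It was also 0 with only the late arrays on shared slides and without the pairs low on chromosome X, both chosen after seeing the data. The call also ended without early replicate 1, 2 or 5 or late replicate 4 or 6, with 0 regions each. Without late replicate 1 or 2, 571 and 527 regions passed, and without early replicate 4, 2.

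No region passed between late and preleukemic pairs in limma, where 2787 had an unadjusted p under 0.05, nor between early and preleukemic pairs, where 184 did. With slide as a block, both counts were again 0. The regions with the smallest p between late and preleukemic pairs, none past the threshold, had differences of 1.46 at Lphn3 (now Adgrl3), 2.26 at Nr2f1, 2.59 at Otx2, -1.08 at Nyx on chromosome X and -0.56 at A930037G23Rik (now Iffo1), all with adjusted p = 0.0863. On the 3 slides with both stages, the late value lay above the preleukemic one by 0.31, 1.77 and 0.17 at Otx2, by 0.21, 2.27 and 0.86 at Nr2f1 and by 0.67, 1.95 and 0.22 at Lphn3. Sfpi1 differed by -0.58 (SE 0.51, adjusted p = 0.486). The late minus preleukemic count moved to 1027, 992 and 540 without late replicates 1, 2 and 6. It was 2791 with the 4 late arrays on slides of their own, an alternative added after seeing the data, and 0 with the 3 on shared slides.

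As lists, 9 of 16 differed between late and preleukemic pairs in camera. Polycomb-type factors (median difference 1.30, adjusted p = 8.5e-25), Hox genes (0.97, adjusted p = 1.8e-07), B cell genes (0.90, adjusted p = 0.0208), stem and progenitor genes (0.54), tumour suppressors (0.52) and Wnt inhibitors (0.35), each of these 3 at adjusted p = 0.0281, were higher in late pairs. Germ cell genes (-0.29, adjusted p = 0.0339), cell cycle regulators (-0.16, adjusted p = 0.0147) and constitutive genes (-0.11, adjusted p = 0.0415) were lower. Adjusted over the list alone, 106 Polycomb-type, 9 tumour suppressor, 6 B cell, 4 Wnt inhibitor and 1 Hox region were higher in late pairs, 1 tumour suppressor and 1 B cell region were lower, and the stem cell, germ cell, cell cycle and constitutive lists had 0 (limma; over all regions 0 in every list, with 2787 regions at an unadjusted p under 0.05). With an estimated correlation no list passed (adjusted p = 0.63 to adjusted p = 0.799). Under within-array loess Polycomb-type factors and Hox genes alone of the 9 passed, and the others had camera adjusted p = 0.0517 to adjusted p = 0.101. Age differs with stage, and with the age covariate Polycomb-type factors alone of the 9 passed. Hox genes (adjusted p = 0.579), B cell genes (adjusted p = 0.629) and the 5 lists of stem cell, tumour suppressor, Wnt, cell cycle and constitutive genes (adjusted p = 0.242 to adjusted p = 0.272) did not, and germ cell genes turned (adjusted p = 0.0772). Without chromosomes X and Y, germ cell genes (adjusted p = 0.0575) and constitutive genes (adjusted p = 0.077) did not pass. With slide as a block, Polycomb-type factors alone passed (adjusted p = 0.000489; Hox adjusted p = 0.478). On each of the 3 slides that held both stages, the late minus preleukemic difference was taken region by region. Its median over the list was -0.02, 0.64 and -0.11 for Polycomb-type factors, -0.03, 0.58 and -0.19 for Hox genes, 0.08, 0.37 and -0.26 for B cell genes and 0.01, -0.04 and -0.03 for cell cycle regulators.

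The spread of log2 ratios over regions, a measure of how far the 2 profiles of a pair lie apart, was wider in late pairs. Its standard deviation per array was 0.432 ± 0.0630 (SD, n = 7) in preleukemic, 0.423 ± 0.0341 (n = 5) in early and 1.09 ± 0.668 (n = 7) in late pairs. The late minus preleukemic difference was 0.661 (two-sided exact permutation p = 0.00816, adjusted p = 0.0245 over 3 tests). The late minus early difference of 0.670 did not pass (exact p = 0.0505, adjusted p = 0.0758), nor did the early minus preleukemic difference of -0.00896 (exact p = 0.777). The late minus preleukemic difference was 0.332 under normexp (adjusted p = 0.0472) and 0.191 with the authors' values, where the call ended (adjusted p = 0.121). It also ended for the interquartile range (0.641, adjusted p = 0.122) and without any 1 preleukemic array (0.645 to 0.674, adjusted p = 0.0758), and stayed without any 1 late array. The late minus early difference passed without early replicate 3 (0.675) or 5 (0.682) or late replicate 1 (0.783), each at adjusted p = 0.0455, and did not pass with any other early or late array left out. Late replicates 4, 5 and 7 had values of 1.84, 1.66 and 1.89, and late replicate 1 had 0.414. On the 3 slides with both stages the late and preleukemic values were 0.489 and 0.485, 0.695 and 0.513, and 0.414 and 0.467.

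Gained regions in late pairs carried a gene name less often than other regions. Among 11227 regions with a gene name 18.1% gained, against 28.9% of 1379 regions named by coordinates only (Fisher's exact test across regions, which are not independent replicates, adjusted p = 5.4e-19). Lost regions went the other way, with 15.6% of named regions and 152 of the 1379 unnamed ones (adjusted p = 1.3e-05), a difference that ended under within-array loess and without late replicate 4 (adjusted p = 0.0914) or 5 (adjusted p = 0.315). The wild-type signal of these late classes was read on the preleukemic arrays, so from other animals. Gained regions had a median at percentile 47.5 ± 3.52 (SD, n = 7 preleukemic arrays), lost regions at 39.2 ± 2.14 and regions not called at 53.5 ± 1.09.

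Chromosome X stood apart in 2 pairs. In preleukemic pair 4 the median log2 ratio of chromosome X regions lay below that of the other chromosomes by -0.71, and in late pair 4 by -2.02, while the other 17 arrays lay between -0.48 and 0.36. Without these 2 pairs, left out together after seeing the data, 153 regions changed in preleukemic pairs (126 gained, 27 lost) and 2668 in late pairs (1534 gained, 1134 lost). Late pair 4 was also among the late arrays with the highest Polycomb-type and Hox medians. Chromosome X lay below the other chromosomes in every late array, by -0.48 to -0.05 apart from pair 4. Preleukemic and early arrays lay on both sides, up to 0.36 and 0.20.

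**Figure D4:**
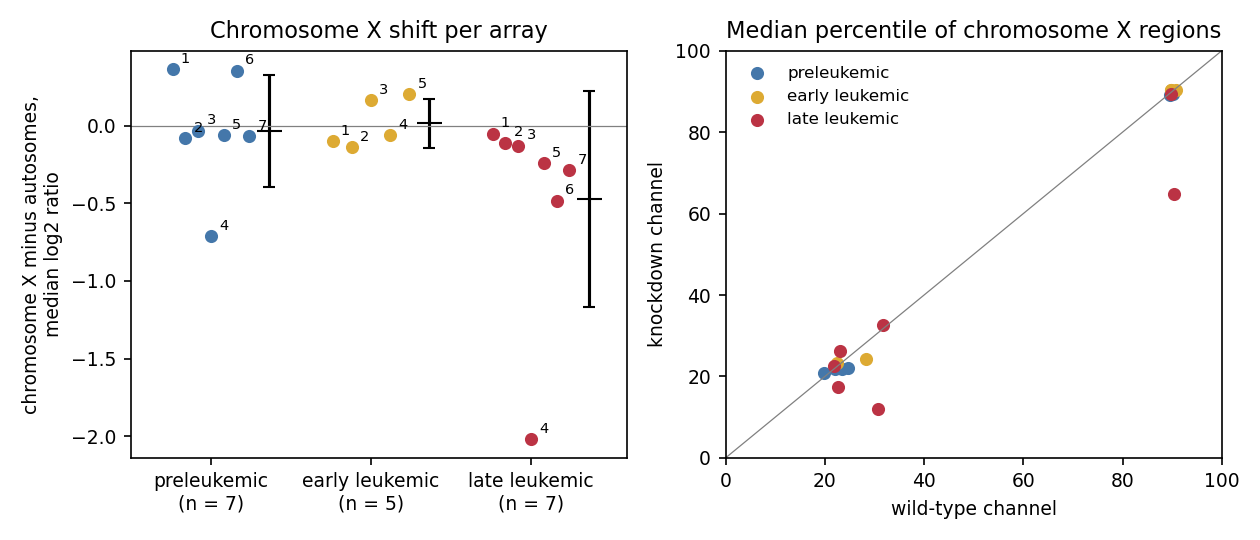
Left, median log2 ratio of chromosome X regions minus that of the other chromosomes per array, with the stage mean and SD as a bar; right, median signal percentile of chromosome X regions in the wild-type channel (horizontal) and the knockdown channel (vertical), 1 point per array. Late replicate 4 lies lowest on the left, at -2.02, and farthest from the line of equality on the right.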

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

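Of the tests in this part, those of centring, of the spread shared between stages, of the sex of late pair 4 and of age were chosen only after their results were seen, as were the fits of late arrays by slide; the rest were set out beforehand.

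Methylated DNA gained in late leukemic pairs over 2433 regions, most of all at Polycomb-type factors. The centring step is argued against as its source, since 2342 regions gained without it. The fit without centring kept the scanner's linear dye normalization, so scaling of the channels as such was not tested. The balance of gains and losses rests on centring, as 3196 regions lost without it against 1901 with it. The number of regions past the threshold depends on the spread shared between stages: with late arrays alone in the fit 13 regions passed. The slides that held late arrays alone and were scanned last cannot be told apart from the stage, since over the 3109 regions gained on them the late array differed from the preleukemic array of its own slide by medians of -0.0130, 0.586 and -0.0392 on the other 3 slides. A gain in some late mice, which differ in age and may differ in disease burden, stays open as an untested biological explanation.

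Tnfaip8, Fosb, Ebi3, Sfpi1 and others, 25 regions in all, changed in all 3 stages. Passenger DNA linked to the engineered PU.1 gene is argued against as the source for most of them, since 1 of the 25, the PU.1 gene itself, lies within 10 Mb of it and the 25 lie on 14 chromosomes. A dye effect of the probes cannot be told apart from a constant genotype difference, as no array had exchanged dyes. The mean change turned to its direction was 2.22 ± 0.310 (SD, n = 7) in preleukemic and 2.04 ± 0.545 (n = 7) in late arrays (exact permutation p = 0.464). Unlinked strain variants and an effect of low PU.1 itself were not tested.

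Chromosome X regions lay below the other chromosomes by -0.713 in preleukemic array 4, with the nearest array of its stage at -0.0794, and by -2.02 in late array 4, with the nearest at -0.483. Mice of different sex are argued against in preleukemic pair 4, whose channels had chromosome X medians at percentiles 90.1 and 89.4, within the upper cluster of channels (89.1 to 90.9). They are argued against in late pair 4 as well, since its knockdown channel stood at percentile 64.7, above the lower cluster (12.0 to 32.7), against 90.3 for wild type. A weaker knockdown channel overall is argued against in late pair 4, where chromosome X lay -2.19 (SE 0.0658) from autosomal regions of equal wild-type signal, but stays open in preleukemic pair 4, where that value was -0.508 (SE 0.0507), at the bound of 0.5 set for it. A mixture of cells that lost methylated X chromosomes is a candidate explanation for late pair 4 that was not tested.

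Other values stood far from the rest of their group, in 13 of 184 groups tested together with the chromosome X values above, while chance alone puts about 1 in 20 groups there. In preleukemic array 7 Myh14 had a log2 ratio of 0.44, with the nearest array at 1.56. In early array 1 Rap2ip stood at 0.82, with the nearest at 2.96, and Adam11 at 0.95, with the nearest at 2.67. Mapk11 stood at 1.68 in early array 4, with the nearest at 1.35. Cdkn1a stood at -3.49 in late array 5, with the nearest at -1.40. The median of myeloid effector genes was 0.028 in early array 3, with the nearest at -0.05, and that of cell cycle genes 0.17 there, with the nearest at -0.0027. The Polycomb-type median was -0.14 in early array 1, with the nearest at 0.02. The median of T and NK cell genes was 0.75 in late array 5, with the nearest at -0.06. In preleukemic array 4 the median of imprinted genes was -0.63, with the nearest at 0.12, and that of germ cell genes -0.94, with the nearest at 0.11.

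Between stages, the SD of region log2 ratios was higher by 0.661 in late than in preleukemic pairs, Ebi3 differed by -1.90 between late and early pairs, and 9 gene lists differed between late and preleukemic pairs.

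Other assignments of the arrays were counted for each fit. The sign of some arrays of a stage was turned. In preleukemic pairs 2 of 64 assignments, the real one included, gave as many regions as the real 67. The assignment with array 4 turned gave 177, so the count does not single out the real assignment. As many lists as the 4 preleukemic shifts were called in 2 of 64 assignments (highest other 4). For the 28 regions and 2 list shifts of early pairs, 16 assignments are too few for a share under 0.05 (1 of 16 each, highest other 0 regions and 1 list). For late pairs 1 of 64, the real assignment, gave as many as 4334 regions, and 3 of 64 gave as many as 10 list shifts. The preleukemic and late shares are under 0.05 but were not adjusted over these tests. Other late assignments reached 3430 regions and 10 lists, so these counts alone do not exclude chance. No split can give fewer regions than 0, so the splits decide nothing for the 0 regions that differed between early and preleukemic pairs (100 of 100 splits, highest other 0; limma, 184 at an unadjusted p under 0.05) or between late and preleukemic pairs (100 of 100, highest other 1; 2787 at an unadjusted p under 0.05). Chance cannot be excluded for the 9 list shifts between late and preleukemic pairs (5 of 100, highest other 9) or for the 1 region that differed between late and early pairs (5 of 100). One of the latter splits gave 1999 regions, which points to a structure of the samples other than stage.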

How the results depend on the processing

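The fits of late arrays by slide and without the pairs with low chromosome X were chosen after seeing the data; every other alternative was planned. Early minus preleukemic counts stayed at 0 under every alternative run (limma, 184 regions at an unadjusted p under 0.05). P values of the SD differences and of the annotation classes were adjusted within each alternative as in the fit reported. Of 134 named values, those that kept direction and side of the threshold numbered 129 without centring, 108 under normexp, 120 under loess, 109 with the authors' values, 107 with array weights and 52 with the age covariate. A small number of arrays and wild-type signal above background at 27.5% of probes in late replicates 5 and 6 limit all values. Except where fewer arrays entered, the cause of a change was not tested. The late minus early count, 1 here, was 0 under loess, the authors' values, single probes, stages alone, array weights, trend and robust variances, age, the replicate block, slide as a fixed block, shared-slide late arrays and without the low chromosome X pairs (limma, 2445 at an unadjusted p under 0.05).

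Under normexp 2109 preleukemic, 200 early and 7851 late regions changed, 1 differed between late and preleukemic and 5 between late and early pairs, and overlaps were 183 (preleukemic and early), 1849 (preleukemic and late) and 176 (early and late). There the late log2 ratios turned to 0.74 at Sycp3, 0.0014 at Ezh2, 0.0027 at Chek2 and 0.15 at Cdkn1a, and the shifts turned for Hox genes in early (adjusted p = 0.951) and germ cell genes in late pairs (adjusted p = 8.7e-05). Under loess 5 of 64 list shifts passed, the preleukemic germ cell shift turned (adjusted p = 0.972) and the log2 odds of loss in named regions fell to 0.121. The late minus preleukemic SD difference did not pass with the authors' values (0.191, adjusted p = 0.121) or for the interquartile range (0.641, adjusted p = 0.122). With the authors' values 148, 54 and 2733 regions changed in preleukemic, early and late pairs, with single probes 367, 161 and 17981 probes, with each stage alone 320, 74 and 13, and with array weights 1133, 140 and 701. With trend and robust variances 23 preleukemic and 11 early regions changed. Without centring 2342 late regions gained and 3196 lost, and without a filter on dim probes 2642 and 3166. With the age covariate 17 early and 53 late regions and 15 list shifts passed. Then 8 of the 9 lists that differed between late and preleukemic pairs did not pass. Polycomb-type factors passed in preleukemic (adjusted p = 2.8e-12) and early pairs (adjusted p = 2.5e-12), Hox genes in preleukemic pairs (adjusted p = 2.1e-05) and B cell genes in early pairs (adjusted p = 0.0215). These stage values are predictions at the mean age of all 19 mice, which no early mouse had reached. Germ cell genes turned with that covariate in early (adjusted p = 0.579) and late minus preleukemic pairs (adjusted p = 0.0772). The replicate block gave 4 early regions. Without chromosomes X and Y 19 list shifts passed; 6 ended, with adjusted p from 0.0536 to 0.077. A 1000 bp gap turned Hoxb5 to -0.15 in preleukemic pairs. The estimated correlation left 0 list shifts (camera). Without the low chromosome X pairs 153 preleukemic and 2668 late regions changed.

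With late arrays on shared slides 292 late regions and 5 list shifts passed. Tdrd6 (-0.038) turned, as did a Pax5 region (start 44725193, -0.0041) other than the one reported above. With late arrays on their own slides 5416 changed, 2791 differed from preleukemic and 2529 from early pairs.

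Leaving out 1 array at a time, changed regions ranged from 39 to 137 in preleukemic, 5 to 35 in early and 2790 to 4871 in late pairs, and differing regions from 0 to 1027 (late minus preleukemic) and 0 to 571 (late minus early). List shifts ranged from 12 to 25, the SD difference from 0.528 to 0.774 (late minus preleukemic, ended without any 1 preleukemic array) and 0.537 to 0.783 (late minus early), overlaps from 5 to 31 (preleukemic and early), 35 to 74 (preleukemic and late) and 5 to 32 (early and late), and the log2 odds of loss from 0.237 to 0.739.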

Other observations

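The test of age below was chosen only after its result was seen, and the genes of the next paragraph were chosen after their values were seen.

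Among myeloid regulators in late pairs, methylated DNA moved in both directions, as it did over all regions. At Runx1, a core transcription factor of definitive blood formation, it fell at a pair of regions (log2 ratios -1.87, SE 0.54, and -0.78, SE 0.17; n = 7, limma). It fell by less at Junb (-0.49, SE 0.13), Id2 (-0.41, SE 0.14), Egr1 (-0.32, SE 0.10), Fli1 (-0.26, SE 0.10) and Myb (-0.25, SE 0.09). It rose at Irf4, which acts in lymphocytes and dendritic cells (1.49, SE 0.44). Meis1, a Hox cofactor, rose in the stem and progenitor list (2.28, SE 0.53), and the imprinted gene Igf2 rose in its list (1.28, SE 0.37).

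The median log2 ratio of chromosome 15 lay above that of the other autosomes by 0.32 in late array 7, by 0.27 in late array 4 and by 0.08 in late array 3, none of which stood apart from the rest of the stage by the test used for single arrays above. Medians were taken for every chromosome, and chromosome 15, not named in advance, is the only autosome given here. Late arrays 4 and 7 shared a slide and had wide spreads over all regions (SD 1.84 and 1.89).

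Age was examined as a candidate explanation for the wide spread of some late arrays. Across the 7 late pairs the SD of region log2 ratios rose with age of the knockdown mouse (Pearson r = 0.837, exact permutation p = 0.0198, adjusted p = 0.0397; Spearman rho = 0.837, exact permutation p = 0.0302, adjusted p = 0.0603; 2 groups tested). Without the 2 mice farthest from the median age r was 0.836. Across the 7 preleukemic pairs r was 0.71 (exact permutation p = 0.0833) and rho 0.704 (exact permutation p = 0.105), and r was 0.376 without the 2 farthest mice. The 4 late arrays on slides of their own held the 4 oldest late mice, so age and slide cannot be separated here, and the relation is a hypothesis.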
